A study of Arabidopsis thaliana with 6 samples.

How the data were processed

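Small RNA was sequenced from 10-day-old Arabidopsis thaliana Col-0 seedlings of 3 genotypes, wild type (WT), parg1-1 and parp1parp2, each untreated or given 100 nM flg22, a peptide from bacterial flagellin that plants sense as a sign of bacteria. Each of the 6 combinations holds 1 library. Per the labels' protocols, RNA was extracted with TRIzol, small RNA was recovered from a gel, libraries were made with a NEBNext small RNA kit, and the barcoded libraries shared a sequencing lane. The seedlings had been moved from agar plates into water the day before treatment. The duration of the flg22 treatment is not given in the sources used here.

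The authors deposited, for each library, whole-number read counts over a fixed list of 679 genomic intervals, named as 337 mature miRNAs, 334 star strands (the partner strand of the miRNA duplex) and 8 TAS loci. Per the submitters' processing notes, Bowtie 0.12.8, bedtools and the TAIR10 genome were used, with no role or order given. The rule that assigned reads to intervals is not given in the sources used here. All 337 mature intervals and 54 star intervals coincided with mature miRNAs annotated on the TAIR10.1 reference, which supplied coordinates and gene context.

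The counts show part of how reads were assigned. The intervals hold 563 distinct sequences, and 82 of these stand at more than 1 locus, filling 198 loci. None of the 82 sequences (0) had different counts at its loci in any library, so a read of such a sequence appears to be counted at each of them. Among 11 pairs of loci shifted by 1 or 2 bases with at least 50 counts in the higher, 10 had under 20% of that count in the other, and the highest share was 54.5%. The 8 TAS loci had 0 counts, and 273 loci were at 0 in every library.

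Total counts per library ran from 247508 to 408805 over all loci, and from 119798 to 187728 with each distinct sequence counted once. A count of 0 allows up to 3 counts, which is between 7.34 and 12.1 CPM (counts scaled to a common library total). The reads were amplified by PCR and no molecular identifiers are named in the labels, so intervals and this limit cover counting error only. As a check for a library deposited more than once, counts of each pair of libraries were compared by chi-square over degrees of freedom. The values ran from 15.3 to 78.1, where sampling noise alone gives about 1.

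Tests used an additive model of genotype and treatment on the deposited counts, because no group has a replicate. It was fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided; R 4.3.3, limma 3.58.1) with TMM scaling. Loci with at least 10 counts in at least 2 libraries entered, which left 187 loci with 136 distinct sequences, and Benjamini-Hochberg adjusted p under 0.05 was called. The model leaves 2 residual degrees of freedom, and its residual holds library noise and any genotype-specific response together. Nothing in the labels says that libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The biological coefficient of variation was 22.8%.

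Pairs of single libraries were described without a test, as the ratio of TMM-scaled counts with an exact conditional binomial (Clopper-Pearson) 95% interval. A locus was counted as apart at a ratio of at least 2, with at least 50 counts in the higher library and an interval excluding equality. The difference of the flg22 log2 ratio of a mutant from that of WT has a 95% interval from a normal approximation to the counts of its 4 libraries, which must all be above 0. Correlations across loci used a prior count of 0.5 and carry no p, since loci are not independent replicates. Where both mutants were compared with the same WT libraries, 100 simulated sets of unchanged libraries gave the value that shared controls produce with no effect. A further edgeR model, chosen after the results were seen, added to the additive one a term for the flg22 response of 1 mutant, with 1 residual degree of freedom. For parp1parp2, and for parg1-1 with identical sequences counted once, it took the spread around the trend as common to all loci, with infinite prior degrees of freedom. The parg1-1 fit of loci as deposited had 8.47.

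The 12 lists of miRNA families, the rule for naming miRNAs and the tests were set before the data were examined. Lists with at least 3 tested loci were tested with camera, at a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over lists for each contrast. In single pairs the median of a list was placed among 10000 random lists of the same size matched on mean expression. The naming rule takes up to 10 miRNAs per direction and contrast among those past the additive test, by size of change. Where fewer than 5 pass, it also takes the 5 with the smallest p. It takes up to 5 per direction among those apart in a pair, any tested member of families 393, 160, 167, 398, 773, 472, 825, 168, 162 and 403, and the 5 with most counts. One member per family and strand is named.

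The fit was tested on simulated counts for the 136 distinct sequences, in 20 runs per contrast with 15 sequences changed 2-fold and 15 changed 4-fold. For flg22 it recovered 56.6% of the 2-fold and 96.4% of the 4-fold changes, with 0.65 false calls per run. For parg1-1 the values were 38% and 87.9% with 0.55 false calls, and for parp1parp2 29.7% and 83.7% with 0.75. For parp1parp2 against parg1-1 they were 32.8% and 85.5% with 0.85. The main calls come from the fit of 187 loci, which was not simulated and had 7.93 prior degrees of freedom, against 53 here. The shares above therefore do not give its recovery. The term for the response of 1 mutant recovered 3.8% and 22.2% in parg1-1 with 0.35 false calls, and 4.2% and 23.3% in parp1parp2 with 0.3.

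Alternatives set beforehand were DESeq2 1.42.0 size factors or its test, total-count scaling, no filter, a filter of 50 counts in 3 libraries, sums per family, dropping a model term, leaving out each library or genotype, and minimum counts of 20 and 200 for pairs. Counting identical sequences once, alone or with DESeq2, with left-out libraries or with a GC offset, was chosen after seeing the data, as was the search for opposite directions between pairs. So were the alternatives for the differences of response, for the overlap of the mutants and, beyond estimated correlation and fry, for the set tests. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The counts cover miRNA and TAS loci, so transcripts of the mutated genes and of DAWDLE were not analysed here, and the genotype labels could not be checked on them.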

Results

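Small RNA libraries of Arabidopsis seedlings were compared across genotypes that differ in poly(ADP-ribosyl)ation, the attachment of ADP-ribose polymers to proteins. PARP enzymes add the polymer and PARG enzymes remove it. The study's title concerns a role of DAWDLE, a protein that acts in miRNA biogenesis, in immunity. With 1 library in each of the 6 groups, no difference between a pair of libraries has a replicate check. Total counts were 284814 in untreated WT and 408805 in WT with flg22. They were 350874 and 330286 in parg1-1, and 278906 and 247508 in parp1parp2, untreated and with flg22.

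A few miRNAs held most of the counts in every library. miR398b, miR159a, miR159b, miR166a and miR158a together took between 54.0% and 59.1% of the counts over distinct sequences. miR398b, which targets transcripts of copper/zinc superoxide dismutases, had 159121 counts over the 6 libraries, and miR159a, which targets MYB transcription factors, had 110924.

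The first comparison asked which miRNAs responded to flg22 across the genotypes. No miRNA passed the test. miR168b-star had the smallest p, with a log2 fold change of 0.81 ± 0.27 (SE), and failed correction (edgeR adjusted p = 0.996). Its scaled count was higher with flg22 in 3 of 3 genotypes. miR393a-star (0.52 ± 0.26), miR156f-star (1.03 ± 0.52), miR398a (0.98 ± 0.53) and miR173-5p-star (-0.92 ± 0.42) followed, with the same adjusted p. The value of miR398a came from parp1parp2, with 141 scaled CPM untreated and 1069 with flg22, against 824 and 865 in WT and 91.7 and 92.7 in parg1-1, and was 0.05 without untreated parp1parp2 and 0.15 without parp1parp2 with flg22. That of miR156f-star, with 2 to 20 counts per library, was 0.47 without untreated WT, 0.52 without WT with flg22, 1.62 without untreated parp1parp2 and 1.75 without parp1parp2 with flg22. In all, edgeR called 0 of 187 loci, with 1 at an unadjusted p under 0.05, and DESeq2 called 0, with 1. Without the untreated parp1parp2 library 3 loci were called, all higher with flg22.

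Families linked to immunity had no call for flg22. Of the list reported to rise after flg22 or bacteria, which holds miR160, miR167 and miR393 and acts on auxin signalling, 0 of 17 loci passed, and 0 when adjusted over the list alone. Its median log2 fold change was -0.18 (camera adjusted p = 0.814). In WT alone the list had a median log2 ratio of -0.027, at percentile 91.4 of random lists. With identical sequences counted once it was 0.17 in WT (percentile 94.7), with 10 of 13 sequences higher. The sign in WT thus depended on this choice. In that setting the median was -0.14 in parg1-1 (percentile 18.9) and -0.0033 in parp1parp2 (percentile 31.2). miR393a, which targets the TIR1 and AFB auxin receptors, had log2 ratios of flg22 to untreated of -0.05 in WT (95% interval -0.85 to 0.77), -1.01 in parg1-1 (-2.26 to 0.14) and 0.09 in parp1parp2 (-0.86 to 1.04). It rested on 10 to 34 counts per library, so changes of this size were not detectable at this depth. miR393b-star, with 649 to 1123 counts, had 0.16 in WT (0.02 to 0.29), -0.10 in parg1-1 and 0.10 in parp1parp2. miR160a, which targets auxin response factors, had -0.04 in WT (-0.16 to 0.09), -0.61 in parg1-1 (-0.77 to -0.45) and -0.00022 in parp1parp2 (-0.13 to 0.13). With identical sequences counted once, the ratios of the WT pair lie higher (miR395b 1.33 against 1.16), so small values in WT depend on the scaling.

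Of the list reported to fall after pathogen patterns or infection, 0 of 13 loci passed, and 0 when adjusted over the list alone, with a median of -0.0065 (camera adjusted p = 0.814). miR398b, whose locus overlaps an exon of AT5G14550 on the other strand, had log2 ratios of -0.27 in WT, -0.09 in parg1-1 and 0.35 in parp1parp2. miR472, in an exon of AT1G12290, targets transcripts of NLR immune receptors, and had -0.10, -0.18 and 0.25, each with an interval that included 0. miR825 had 0.87 in WT (0.19 to 1.60), -0.38 in parg1-1 (-1.14 to 0.36) and -0.08 in parp1parp2 (-0.90 to 0.73). None of the 12 lists (0) passed camera for flg22, the smallest adjusted p being 0.0727, for regulators of the small RNA machinery.

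**Figure D1:**
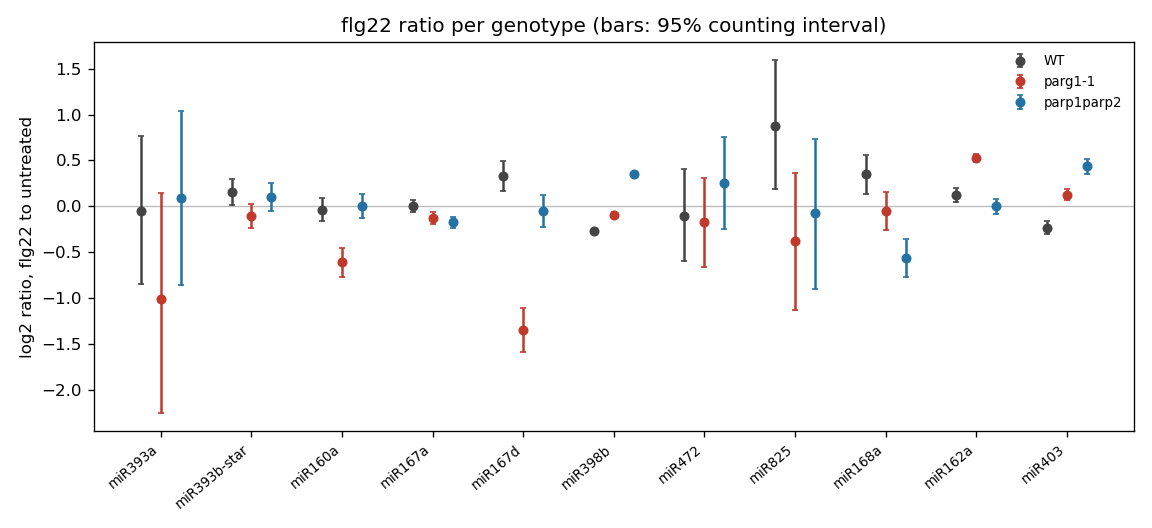
Log2 ratio of TMM-scaled counts, flg22 to untreated, for 11 miRNAs of the families chosen beforehand, with 1 library on each side and colours for the genotypes. Bars are 95% counting intervals, and miR167d in parg1-1 lies lowest at -1.35.

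Within single genotypes, small sets of miRNAs differed between the flg22 and the untreated library. In WT, miR395b, which targets sulfate assimilation genes, had a log2 ratio of 1.16 (0.74 to 1.59), and miR400, in an intron of AT1G32583, had -1.07 (-1.70 to -0.46), or -0.90 and no longer 2-fold apart with identical sequences counted once. In parg1-1, miR158a-star had 1.33 (1.05 to 1.61) and miR167d, which targets auxin response factors, had -1.35 (-1.60 to -1.11). In parp1parp2, miR398a had 2.92 (2.44 to 3.43) and miR159C 2.08 (1.64 to 2.53), both uncertain because each differs at 1 base from a far more abundant miRNA, while miR395b had -1.55 (-2.10 to -1.04) and miR399b, which acts on the phosphate regulator PHO2, had -1.14 (-1.49 to -0.80). In all, 7 loci were at least 2-fold apart in WT, 2 in parg1-1 and 7 in parp1parp2. With identical sequences counted once these were 3, 2 and 4.

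The flg22 ratios were compared between genotypes across loci, which are not independent replicates. Log2 ratios in WT and parg1-1 correlated at r = 0.112 (rho 0.0731), those in parg1-1 and parp1parp2 at r = 0.111 (rho 0.154), and those in WT and parp1parp2 at r = -0.402 (rho -0.341). Summed per family these were 0.309, -0.242 and -0.304, and with identical sequences counted once 0.0443, 0.0604 and -0.293. At a minimum of 50 counts in every library, r for WT and parg1-1 was 5.57e-05. The difference of the flg22 response from WT reached 2-fold, with an interval excluding 0, for 9 loci in parg1-1 and 17 in parp1parp2, or 5 and 8 with identical sequences counted once. In parp1parp2 they included miR398a (2.85, 2.32 to 3.38) and miR395b (-2.71, -3.37 to -2.06), and in parg1-1 miR167d (-1.68, -1.96 to -1.40). These differences from WT were not tested, since a model with a separate response for each genotype leaves no residual.

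A term for the flg22 response of 1 mutant, set against the response that the other 2 genotypes share, leaves 1 residual degree of freedom and was added after the results were seen. In parp1parp2 the response was higher for miR398a, by a log2 difference of 2.86 ± 0.46 (SE; edgeR adjusted p = 5.42e-07), miR159C (2.66 ± 0.44) and miR400 (1.68 ± 0.56, adjusted p = 0.0493). It was lower for miR395b (-2.49 ± 0.46, adjusted p = 6.22e-06), miR395a (-2.92 ± 0.77) and miR399b (-1.57 ± 0.42). These 6 sequences stand at the 11 loci called of 187, 3 higher and 8 lower, where DESeq2 called 5. With identical sequences counted once edgeR called 5 sequences, without miR400, and DESeq2 3. The term rests on the 2 parp1parp2 libraries, so a deviation of either would give the same result, and miR398a and miR159C are uncertain as above. In parg1-1 edgeR called 0 loci, with 2 at an unadjusted p under 0.05, and DESeq2 0, with 1. With identical sequences counted once, the fit recovered 22.2% of simulated 4-fold changes there, so simulated responses of that size were mostly missed. The fit of loci as deposited was not simulated. The absence of calls in parg1-1 therefore does not exclude responses of that size.

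The second comparison asked which miRNAs differed in parg1-1. miR162a, which targets the transcript of the miRNA-processing enzyme DCL1, rose by a log2 fold change of 1.27 ± 0.21 (SE; edgeR adjusted p = 0.00824). Its level was 8770 and 9555 scaled CPM in WT and 18280 and 26370 in parg1-1, untreated and with flg22. miR162a-star did not pass, with 59.9 and 67.3 scaled CPM in WT and 74.0 and 77.2 in parg1-1. It rested on 17 and 28 counts in WT and 25 and 25 in parg1-1. miR845a, of a family that matches the primer-binding sites of retrotransposons, fell, with a log2 fold change of -2.47 ± 0.32 (adjusted p = 0.00282), from 1779 and 2141 to 343 and 365. miR172a, which targets AP2-like transcription factors, fell (-1.32 ± 0.31), as did miR397b, which targets laccases (-1.21 ± 0.31), and miR157a, which targets SPL transcription factors (-0.95 ± 0.26).

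In all, 20 of 187 loci passed, 4 higher and 16 lower. They hold 10 distinct sequences, each on the same side of WT in 2 of 2 treatments. The others higher were miR158a-star (1.56 ± 0.43) and miR866-3p (1.26 ± 0.33). The mature miR158a did not pass, with 36770 and 29350 scaled CPM in WT and 48480 and 49810 in parg1-1. The others lower were miR398a (-3.21 ± 0.65), miR169h with 6 further loci (-3.05 ± 0.72) and miR170 (-1.81 ± 0.45). miR169h, which targets NF-Y transcription factor subunits, rested on 16 and 19 counts in WT and 3 and 1 in parg1-1. miR398a differs at 1 base from miR398b and had 960 counts against 159121, so its values are uncertain.

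miR845a (CGGCTCTGATACCAATTGATG) lies on chromosome 4 from 12217457 to 12217477 on the minus strand of TAIR10, at AT4G23387. miR162a (TCGATAAACCTCTGCATCCAG) lies on chromosome 5 from 2634936 to 2634956 on the minus strand, at AT5G08185, and its sequence stands at 2 loci. miR172a lies on chromosome 2 from 11942918 to 11942938, and miR397b on chromosome 4 from 7878730 to 7878750. None of these 4 intervals is inside a protein-coding gene of the annotation.

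The number of parg1-1 calls changed when a library was left out, which leaves 1 residual degree of freedom. Over all settings run, the log2 fold change lay between -2.67 and -2.08 for miR845a, 1.00 and 1.53 for miR162a, and -2.06 and -1.59 for miR170. It lay between -4.04 and -2.29 for miR398a, -3.58 and -2.67 for miR169h, -1.47 and -0.995 for miR172a, and -1.35 and -0.98 for miR397b. For miR157a it was -1.30 to -0.55, for miR866-3p 0.94 to 1.63 and for miR158a-star 0.65 to 2.30. Without untreated WT, untreated parg1-1 or parg1-1 with flg22, edgeR called 0 loci, with 20, 27 and 7 at an unadjusted p under 0.05. Without WT with flg22 it called 7, all higher and none of them (0) among the 20. Without parp1parp2 with flg22 it called 2, and without untreated parp1parp2 32. DESeq2 called 12 loci, 10 of them among the 20, and counting identical sequences once gave 12 sequences, 10 of them shared. The parg1-1 library with flg22 stood apart, with a chi-square per degree of freedom of 75.1 and 78.1 against the WT libraries and 24.1 against untreated parg1-1.

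**Figure D2:**
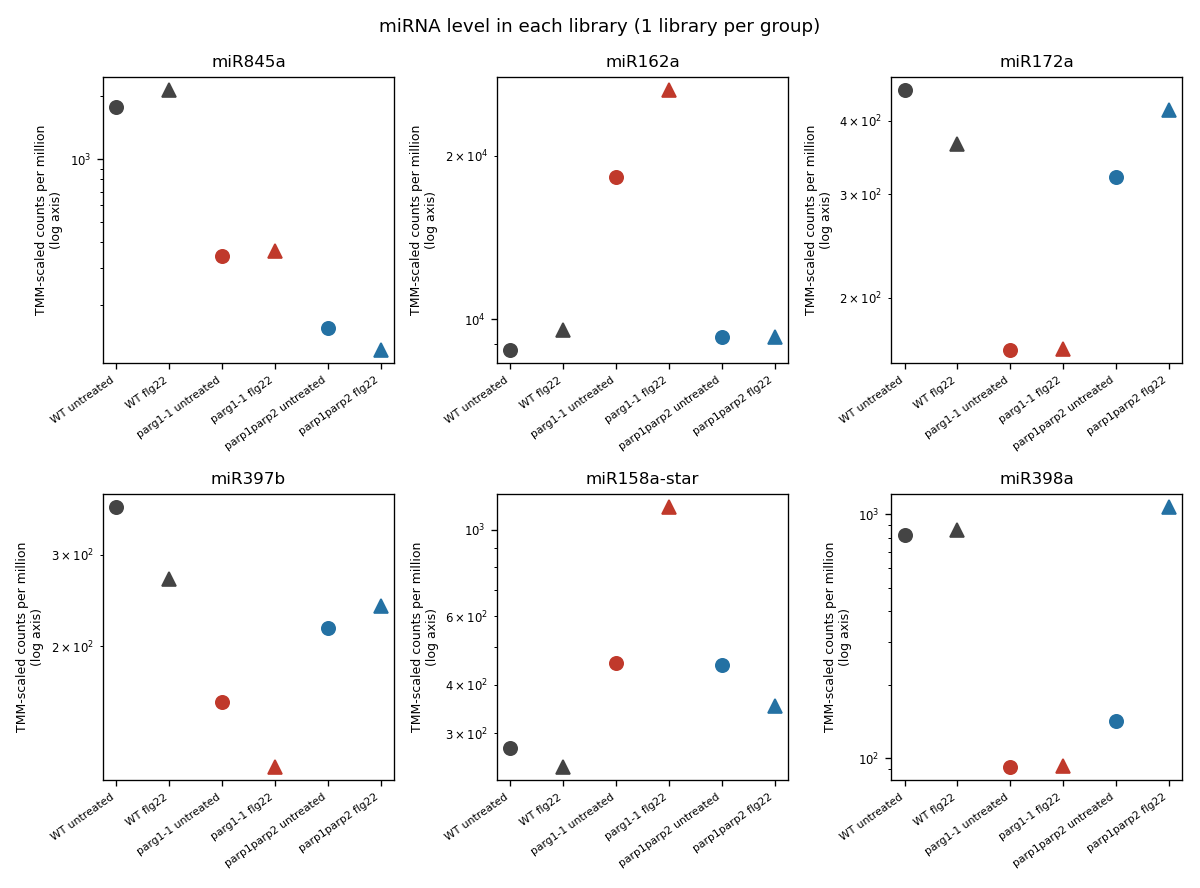
TMM-scaled CPM on a log axis for 6 miRNAs in each of the 6 libraries, with circles for untreated and triangles for flg22. miR845a stood at 1779 and 2141 in WT, 343 and 365 in parg1-1, and 155 and 122 in parp1parp2.

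Among the lists, regulators of the small RNA machinery had 2 of 9 loci higher in parg1-1, both of the miR162 sequence (camera adjusted p = 0.00873; adjusted p = 0.631 with an estimated correlation). miR403, which targets AGO2, had 0.51 ± 0.22 and did not pass. The phosphate, sulfate and nitrogen list had 7 of 23 loci lower, all of 1 miR169 sequence (camera adjusted p = 0.000343; adjusted p = 0.631 with an estimated correlation). The deeply conserved families had 2 of 116 loci higher and 15 lower, and the less conserved 2 of 66 higher and 1 lower (camera adjusted p = 0.02 for each; adjusted p = 0.631 for each with an estimated correlation). The deeply and less conserved lists hold most tested loci between them, and camera sets a list against the other loci. Their opposite results are therefore not independent. The median of the deeply conserved list was -0.08, and 0.013 with DESeq2 size factors. With identical sequences counted once no list (0) passed.

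The remaining lists did not pass camera in parg1-1. The copper list had 2 of 9 loci lower, miR397b and miR398a (adjusted p = 0.162), and the juvenile-adult phase list 5 of 22 lower, of miR157 and miR172 (adjusted p = 0.13). The leaf, meristem and polarity list had 1 of 34 lower, miR170 (adjusted p = 0.111), and the list reported to fall after infection 1 of 13, miR398a (adjusted p = 0.596). No locus (0) passed in the auxin list of 25 or in the list reported to rise after flg22 (adjusted p = 0.136 for each), in the 5 triggers of trans-acting siRNAs (0.596) or in the 6 triggers aimed at NLR or PPR genes (0.926). Adjusted over the list alone, the counts were 2 for copper, 6 for the phase list, 7 for nutrients, 2 for small RNA machinery, 17 for deeply conserved, 1 for less conserved and 1 for the list reported to fall, and 0 for the others.

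In single pairs, miR162a had log2 ratios of parg1-1 to WT of 1.06 (0.99 to 1.13) untreated and 1.46 (1.41 to 1.52) with flg22, and miR845a -2.37 (-2.68 to -2.08) and -2.55 (-2.84 to -2.28). miR158a-star had 2.22 (1.90 to 2.55) and miR157a -1.26 (-1.37 to -1.14) with flg22. In all, 9 loci were at least 2-fold apart untreated, 2 higher and 7 lower (3 and 6 with DESeq2 size factors), and 18 with flg22, 4 higher and 14 lower. The log2 ratios of the untreated and the flg22 pair, which share no library, correlated across loci at r = 0.683 (rho 0.489), or r = 0.568 with identical sequences counted once.

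The third comparison asked which miRNAs differed in parp1parp2. miR845a fell by a log2 fold change of -3.81 ± 0.34 (SE; edgeR adjusted p = 0.00012), from 505 and 891 counts in WT to 45 and 30, lower in 2 of 2 treatments, and was the 1 locus of 187 to pass. DESeq2 also called 1. miR845a-star (-4.25 ± 1.16, adjusted p = 0.402; 10 and 20 counts in WT, 1 and 0 in parp1parp2), miR157C-star (1.09 ± 0.36), miR408-star (-0.89 ± 0.32) and miR157d (-0.90 ± 0.37) failed correction, the last 3 at adjusted p = 0.53. miR162a, called in parg1-1, had 0.02 ± 0.21. The miR845a call was lost without untreated WT (adjusted p = 0.223), without WT with flg22 (0.108) and without parp1parp2 with flg22 (0.0515), each with 1 residual degree of freedom. With identical sequences counted once it was lost in 1 such fit, without WT with flg22 (adjusted p = 0.174), and over all settings its log2 fold change lay between -4.11 and -3.32. In the first 3 fits edgeR called 0 loci, with 4, 19 and 16 at an unadjusted p under 0.05, and without untreated parp1parp2 it called 8.

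In single pairs against WT, miR845a had log2 ratios of -3.52 (-3.99 to -3.08) untreated and -4.14 (-4.72 to -3.62) with flg22. Untreated, miR398a had -2.54 (-3.06 to -2.06) and miR159C -1.82 (-2.28 to -1.39). miR408-star had -1.08 and miR5026 -1.03, and both were under 2-fold with DESeq2 size factors (-0.99 and -0.94) and with identical sequences counted once (-0.79 and -0.74). miR395b had 1.12 (0.68 to 1.58) untreated and -1.59 (-2.12 to -1.10) with flg22. In all, 8 loci were at least 2-fold apart untreated, 3 higher and 5 lower (3 and 3 with DESeq2 size factors), and 8 with flg22, all lower. The log2 ratios of the pairs correlated at r = 0.0555 (rho -0.102). Of the 12 lists, the phosphate, sulfate and nitrogen list passed camera with a median of -0.38 and 0 of 23 loci called (camera adjusted p = 0.00748; adjusted p = 0.831 with an estimated correlation).

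**Figure D3:**
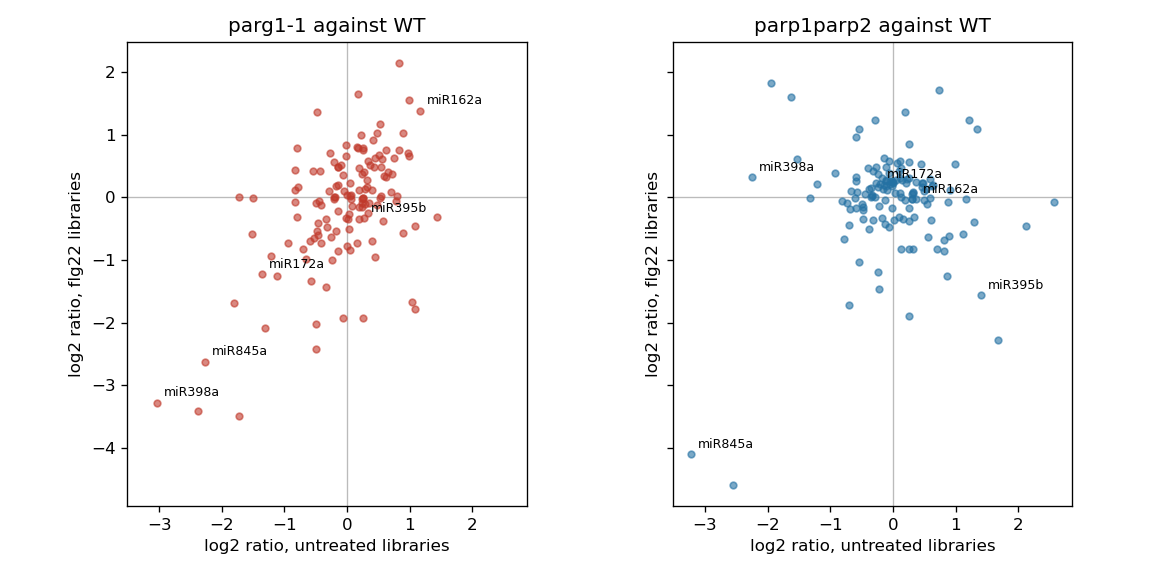
Log2 ratio to WT of scaled counts in the untreated libraries (horizontal axis) and the flg22 libraries (vertical axis), for the 136 tested distinct sequences, each counted once, in parg1-1 and parp1parp2. The ratios correlate at r = 0.568 in parg1-1 and 0.129 in parp1parp2, and miR845a lies low in both.

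Set directly against parg1-1, parp1parp2 had less miR162a, with a log2 fold change of -1.25 ± 0.21 (SE; edgeR adjusted p = 0.0142), in 2 of 2 treatments. The 2 loci of this sequence were the 2 called among 187. miR845a (-1.35 ± 0.33), miR866-3p (-1.38 ± 0.34), miR172a (1.17 ± 0.32) and miR5012 (-1.47 ± 0.40) failed correction, each at adjusted p = 0.105. With DESeq2 size factors 9 loci were called, 3 higher and 6 lower. Counting identical sequences once gave 13 calls, 7 higher and 6 lower, in a fit with 53 prior degrees of freedom against 7.93.

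The call of miR162a between the mutants was lost in 5 of the 6 fits without a library, each with 1 residual degree of freedom, and its log2 fold change lay between -1.47 and -0.85 over all settings. In those 5 fits edgeR called 0 loci, with 24 without untreated WT, 35 without WT with flg22, 16 without untreated parg1-1, 6 without parg1-1 with flg22 and 30 without parp1parp2 with flg22 at an unadjusted p under 0.05. Without untreated parp1parp2 it called 26. Of the 12 lists, 7 passed camera. Medians were above 0 for the juvenile-adult phase (0.36; adjusted p = 0.00183), deeply conserved (0.13; 0.00085), flg22-rise (0.45; 0.00405), auxin (0.19; 0.0072) and nutrient (0.47; 0.0467) lists. They were below 0 for the less conserved (-0.30; 0.00085) and small RNA machinery (-0.69; 0.00607) lists. These lists are not independent, since the families of the flg22-rise list all belong to the auxin list. The deeply and less conserved lists hold most tested loci between them, and camera sets a list against the other loci. With an estimated correlation none of the 7 (0) passed, the smallest being adjusted p = 0.346.

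The differences of both mutants from WT share the WT libraries. They correlated across loci at r = 0.588 untreated, where 100 simulations of unchanged libraries gave a mean of 0.506 and a highest value of 0.657. With flg22 r was 0.561, against a simulated mean of 0.437 and a highest value of 0.609. With identical sequences counted once r was 0.5985 untreated and 0.469 with flg22, against simulated means of 0.5065 and 0.465. Over loci as deposited the covariance was 0.355 against a simulated mean of 0.232 untreated, and 0.486 against 0.191 with flg22. With identical sequences counted once it was 0.3385 against 0.2116 untreated, and 0.364 against 0.181 with flg22. Across treatments, with no library shared, r was 0.27 and 0.243 (rho 0.0273 and 0.0549). Simulated means there were 0.0119 and 0.0097, and the highest simulated values 0.288 and 0.278. The covariances were 0.1775 and 0.193, against simulated means of 0.00488 and 0.00415. With identical sequences counted once r was 0.155 and 0.267, against simulated means of 0.0135 and 0.0136 and highest values of 0.3 and 0.281. Each r was thus above the simulated mean and below the highest simulated value, which does not settle whether the mutants overlap. Over loci as deposited, loci of the same sequence were simulated separately though their real counts are identical. The highest simulated values there may therefore be too low. Of the 16 loci lower in parg1-1 and the 1 lower in parp1parp2, 1 was shared, miR845a, where independent lists, which leave out the shared controls, would share 0.0856. The 100 simulations of unchanged libraries, which leave out any effect, shared 0 lower calls (edgeR), with means of 0.08 calls in parg1-1 and 0.11 in parp1parp2. With so few simulated calls, sharing was hardly possible, so these simulations do not show what shared controls add. miR845a was also lower in pairs that share no WT library. Its log2 ratios were -2.37 in untreated parg1-1 and -4.14 in parp1parp2 with flg22, and -2.55 in parg1-1 with flg22 and -3.52 in untreated parp1parp2. A deviation of a single WT library would not give both ratios of such a combination. A deviation common to both WT libraries would. As miR845a was also chosen by its calls on these same libraries, shared controls are not excluded as the source of this 1 shared call.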

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

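The search for effects that point opposite ways and the test of the flg22 response were chosen after the data were seen. The search covered miRNAs at least 2-fold apart in each direction with counting intervals that exclude equality.

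miR395b, which targets sulfate assimilation genes, was the 1 sequence found with opposite directions. Its log2 ratio of flg22 to untreated was 1.16 in WT and -1.55 in parp1parp2, and its log2 ratio of parp1parp2 to WT was 1.12 untreated and -1.59 with flg22. Both contrasts come from the same 4 libraries and restate the difference of response given above (-2.71), so they are not separate observations. The counts were 62 and 203 in WT, 83 and 132 in parg1-1, and 138 and 40 in parp1parp2, untreated and with flg22. The sequence stands at 3 loci, of which miR395b lies on chromosome 1 from 9364540 to 9364560. The opposite directions themselves were not tested, since each group has 1 library.

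A term for the flg22 response of parp1parp2, against a response taken as shared by WT and parg1-1, was called for 6 sequences. The model leaves 1 residual degree of freedom. With identical sequences counted once edgeR called 5 sequences, without miR400, and DESeq2 called 3. miR398a and miR159C are uncertain, since each differs at 1 base from a far more abundant miRNA. The log2 differences were -2.49 for miR395b, -2.92 for miR395a, -1.57 for miR399b, 1.68 for miR400, 2.86 for miR398a and 2.66 for miR159C (edgeR adjusted p from 5.42e-07 to 0.0493).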

How the results depend on the processing

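Counting identical sequences once, alone or with another change, was chosen after the results were seen. So were all alternatives for the overlap of the mutants and the difference of response, its test included, and set tests on family sums. The rest were set beforehand. The genotype term in the flg22 fit sets each flg22 library against the untreated one of its genotype, and without it calls were also 0 (edgeR, 1 at an unadjusted p under 0.05). Beyond that, no paired analysis by replicate number was possible because each group has 1 library, so groups share a single number.

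Of the single miRNAs named, 401 values under an alternative kept their direction and side of the threshold, 104 kept the direction and were no longer called, 24 became called, and 0 reversed. Of the medians of lists, 144 moved by less than their spread and 47 by more. The median of the deeply conserved list in parg1-1 went from -0.08 to 0.013 with DESeq2 size factors. In the additive contrasts, identical sequences counted once moved the median of all loci in parp1parp2 by 0.14, and no other scaling moved a median by over 0.1. Single pairs moved more. With identical sequences counted once, miR845a in untreated parp1parp2 against WT went from -3.52 to -3.23. For flg22 in WT, miR395b went from 1.16 to 1.33. With DESeq2 size factors, miR398a in untreated parg1-1 against WT went from -3.17 to -3.04.

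For flg22, calls were 0 under each alternative with all libraries (edgeR, 0 to 6 at an unadjusted p under 0.05; DESeq2 0, with 1). Leaving out a library or genotype gave 0 to 3, the 3 being without untreated parp1parp2. With identical sequences once it gave 0 to 1, the 1 being without untreated WT, without both parg1-1 libraries and without both parp1parp2 libraries.

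For parg1-1, the 20 calls became 9 with the filter of 50 counts in 3 libraries, 12 with DESeq2 (83 adjusted p missing), 7 summed per family, and 12 with identical sequences once. The last became 5 with DESeq2 and 10 with a GC offset. Leaving out a library gave 0 to 32, and with identical sequences once 0 to 19: 0 without WT with flg22, 2 without parg1-1 with flg22, 5 without untreated parp1parp2, 9 without untreated parg1-1, 16 without untreated WT and 19 without parp1parp2 with flg22.

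For parp1parp2, the 1 call became 2 with no filter. Leaving out a library gave 0 to 8, and with identical sequences once 0 to 5, the 0 being without WT with flg22 and the 5 without parp1parp2 with flg22. For parp1parp2 against parg1-1, the 2 calls became 9 with DESeq2 size factors, 4 with no filter, 0 with the filter of 50 counts in 3 libraries (edgeR, 22 at an unadjusted p under 0.05), 10 with the DESeq2 test (97 adjusted p missing), 6 summed per family and 13 with identical sequences once. The last became 2 with DESeq2 or a GC offset. Leaving out a library gave 0 to 26, and with identical sequences once 0 to 16, with 8 without untreated parg1-1. A left-out library leaves 1 residual degree of freedom; otherwise the cause was not tested.

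For counts of loci at least 2-fold apart, a minimum of 20 counts gave 11 for flg22 in WT, 9 in parg1-1 and 11 in parp1parp2, 29 for parg1-1 against WT with flg22, and 14 untreated and 15 with flg22 for parp1parp2 against WT. A minimum of 200 counts gave 3 for flg22 in WT and 4 in parp1parp2, 4 untreated and 10 with flg22 for parg1-1 against WT, and 3 and 4 for parp1parp2 against WT. Summed per family, the counts were 2 for flg22 in WT, 0 in parg1-1 and 2 in parp1parp2, 8 for parg1-1 against WT with flg22, and 3 and 2 for parp1parp2 against WT. Identical sequences counted once gave 3 for flg22 in WT and 4 in parp1parp2, 5 and 4 for parp1parp2 against WT, and 5 in parg1-1 and 8 in parp1parp2 for the difference of response. Tested as a term against the other 2 genotypes, the latter was called for 11 loci in parp1parp2 (DESeq2 5) and 0 in parg1-1 (edgeR, 2 at an unadjusted p under 0.05; DESeq2 0, with 1). With identical sequences once it was called for 5 (DESeq2 3) and 0 (edgeR, 7 at an unadjusted p under 0.05; DESeq2 0, with 1). Fewer features enter in the stricter and merged settings.

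The correlation of flg22 ratios for WT with parg1-1, 0.112, became 0.309 summed per family, 5.57e-05 at 50 counts in every library and 0.0443 with identical sequences once (-0.0706 at 50 counts). It became -0.242 for parg1-1 with parp1parp2 summed per family and -0.557 for WT with parp1parp2 at 50 counts in every library. For parg1-1 to WT across treatments it became 0.489 (Spearman), 0.543 (family) and 0.568 (identical sequences once), and for parp1parp2 to WT -0.102 (Spearman) and -0.0912 (50 counts in every library). The overlap of the mutants by Spearman was 0.394 with flg22, and 0.0273 and 0.0549 across treatments, where identical sequences once gave 0.155 and 0.267. The cause was not tested.

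Set tests called 4 lists in parg1-1, 1 in parp1parp2 and 7 between the mutants. With an estimated correlation and with fry these were 0, 0 and 0. As described above, several of the lists are not independent of each other. Fry for either direction called 7 in parg1-1, 1 in parp1parp2 and 0 between the mutants. The 1 was the less conserved list (adjusted p = 0.0238; 0.0491 with identical sequences once and 0.0257 summed per family), which camera did not call. Identical sequences once gave 0, 0 and 3, and sums per family 0, 0 and 4. Depth limits loci such as miR169h, whose counts in parg1-1 were 3 and 1.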

Other observations

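All tests of explanations below were chosen after the results were seen.

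Of the 12 lists in 7 pairs of single libraries, the 10 medians most extreme among random lists are given, chosen after their values were seen and with identical sequences counted once. The copper list had a median log2 ratio to WT of -0.63 in untreated parg1-1, at percentile 0.18 of random lists, and of -0.48 in untreated parp1parp2, at percentile 0.61. Both are set against the same untreated WT library, and with flg22 the list had -0.18 in parg1-1 (percentile 22.9) and -0.014 in parp1parp2 (percentile 23.1). The phosphate, sulfate and nitrogen list had -0.94 in parp1parp2 against WT with flg22 (percentile 0.04) and -0.61 for flg22 within parp1parp2 (percentile 1.32). In WT, the deeply conserved list had 0.08 for flg22 (percentile 99.4; -0.036 over loci as deposited) and the less conserved list -0.12 (percentile 0.8). In parp1parp2 against WT with flg22, triggers aimed at NLR or PPR genes had 0.47 (percentile 99.2) and the list reported to fall after infection 0.30 (percentile 98.7). Both lists hold the families miR400, miR472 and miR825, so their values are not independent. In parg1-1 against WT with flg22, the deeply conserved list had -0.12 (percentile 2.12) and the less conserved list 0.13 (percentile 98.2). Each describes a pair of libraries, and several pairs share a library: both values of the nutrient list hold parp1parp2 with flg22, and all those of the deeply and less conserved lists hold WT with flg22. The deeply and less conserved lists also hold most tested sequences between them, so their opposite values are not independent.

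miR845a was lower in both mutants. A base variant that stops reads of the mature sequence from matching would leave the star strand in place, but miR845a-star had 5 counts in the 4 mutant libraries against 30 in the 2 WT libraries, a scaled ratio of 0.0974 with an upper 95% bound of 0.253. miR845b lies nearby on the same strand of chromosome 4, from 12214086 to 12214107, where miR845a starts at 12217457. It had 2 counts in the mutant libraries against 17 in WT, a scaled ratio of 0.0687 (0.0077 to 0.289). As the loci are close, miR845b may not be independent of miR845a. Removing a GC trend from each library left the parp1parp2 log2 fold change at -3.63 ± 0.32 (SE; edgeR adjusted p = 5.87e-05). A change at the miR845 loci carried by the mutant lines, or an effect of the genotype, may underlie the pattern, and neither was tested.

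The miRNAs changed in parg1-1 were weighed against the parg1-1 library with flg22, which stood apart. Of 13 sequences at least 2-fold apart in the flg22 pair, 12 had the same sign in the untreated pair, which shares no library with it. The median signed log2 ratio of the 13 was 0.989 there (bootstrap 95% interval over sequences 0.502 to 1.31). The parg1-1 library with flg22 alone therefore does not account for the pattern as a set. Sequences are not independent replicates, so the interval does not measure spread between libraries. A GC offset left 99.3% of the median absolute log2 fold change of the 12 called sequences, but 4 of the 12 calls ended: miR157d (-1.24 ± 0.33 before, -1.15 ± 0.36 after), miR157a (-0.94 ± 0.29, -0.89 ± 0.25), miR159C (-1.60 ± 0.38, -1.49 ± 0.54) and miR158a-star (1.58 ± 0.35, 1.45 ± 0.43). Each of these 4 folds shrank and the SE rose for all but miR157a, and the fit with the offset had 8.19 prior degrees of freedom against 53; their parts in the lost calls were not separated. A difference between plates or cultures of single libraries and an effect of the genotype may each underlie the changes, and neither was tested.

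miR398a and miR159C varied widely between libraries, and each differs at 1 of the last positions from a far more abundant miRNA. Reads of miR398b counted at 1 fixed rate would give a constant ratio, but miR398a per miR398b differed 10.3-fold between the highest and the lowest library. A rate of changed end bases that differs between libraries cannot be told apart from real levels. In 6 of 18 settings for choosing pairs of related miRNAs, the pairs that differ at the end varied more than every other pair, but those settings kept no end pairs besides the ones of miR398a and miR159C, so this decides nothing, and in the other 12 miR319C, a further end pair, varied 1.17-fold. The variation may be technical or follow genotype and flg22, which was not tested.

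For flg22 across the genotypes, the real split of the 6 libraries gave 0 called loci (edgeR, 1 at an unadjusted p under 0.05; DESeq2 0), and the highest of the other splits, which also parts every genotype, gave 6. Since the real split gave 0 calls, any split gives at least as many, so this comparison decides nothing. The 10 splits would also be too few for a share under 0.05.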
